A study of Mus musculus with 7 samples.

How the data were processed

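RNA from 7 samples of mouse embryonic fibroblasts was sequenced: 3 samples lacked p53 (p53 KO), 2 lacked both p53 and Mdm2 (p53/Mdm2 KO) and 2 lacked p53 and carried the C462A substitution in Mdm2 (p53 KO with Mdm2 C462A). Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate embryos or cultures. Y-linked genes were high in some libraries of each genotype and barely read in others, which argues against a single culture behind all libraries of a genotype. P-values measure the spread between these samples, which may be partly technical. Libraries were made from total RNA with a TruSeq RNA kit and sequenced as single reads of 50 bp, per the labels' protocols. CASAVA 1.8.2, Bowtie2 2.1.0, DESeq 1.14.0 and the genome build mm9 are named in the submitters' processing notes without their roles. The counting tool, the gene annotation and any strand setting are not given in the sources used here, so reads of overlapping genes and of near-identical gene copies cannot be told apart.

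The deposited table holds 1 value per gene and sample for 29955 gene rows, on a log2 scale after a variance-stabilizing transformation by the authors. Its name speaks of normalized reads, but the values are not linear: a gene with no reads has the value 3.36 in all 7 columns. Inverting the parametric form of the transformation, fixed by that value alone, gave normalized reads, and dividing these by a single step per sample gave whole reads. In each of the 7 samples 100% of the values above 0 lay within 0.05 of a whole number. With M for reads in units of 1e6, recovered totals ran from 28.5 M reads (p53/Mdm2 KO replicate 2) to 41.5 M (p53 KO replicate 2), and 3 reads, the upper limit that a count of 0 allows, corresponded to between 2.65 and 3.86 normalized reads. Such floors cover counting error only. Levels below are recovered normalized reads, given as mean ± SD of a group.

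The test planned before the data were examined was limma on log2 of a linear normalized value plus 1. Because the deposited values were already on a log2 scale, limma 3.58.1 (R 4.3.3) was fitted to them directly, with group means, a mean-variance trend and all 7 samples in 1 fit, which left 4 residual degrees of freedom. The 16900 genes with a mean of at least 10 recovered normalized reads were tested. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are on the deposited log2-like scale, which understates the change of genes with few reads. Of 32 gene lists written before the data were examined, the 30 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with Benjamini-Hochberg adjustment. Camera with an estimated correlation and fry were alternatives. Count tests had been planned as alternatives in case whole reads could be recovered. They were recovered, but edgeR and DESeq2 were not run, because count models were admitted only where the deposited values are counts or linear units. Limma's voom on the recovered reads was added in their place. The correlation of both mutant effects, which share the 3 control samples, was set beside 100 simulated sets of unchanged groups.

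The naming rule fixed before the data were examined took the targeted genes Mdm2 and Trp53, the partner gene Mdm4, the 8 largest rises and 8 largest falls among genes past the adjusted threshold (5 and 5 between the Mdm2 mutants) that had a mean of at least 100 in the higher group and no overlap between replicates, skipping unnamed transcripts, and from each described list up to 4 called members or, where none was called, the 2 with the highest mean. Values of all sex-linked list members were also given. No gene passed the adjusted threshold. The rule for the largest differences was therefore repeated at an unadjusted p under 0.01, and up to 3 list members with the smallest unadjusted p under 0.05 were added. Both steps, and the genes named for single libraries, were chosen after the data were seen. A gene that the rule named in both comparisons with Mdm2 C462A is not reported here.

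The fit was tested on simulated data for 16900 genes at the spread of the real libraries. Among 50 genes changed by 2 on the log2 scale it recovered 28 for p53/Mdm2 KO against p53 KO, 25 for Mdm2 C462A against p53 KO and 26 between the Mdm2 mutants. Among 50 genes changed by 1 it recovered 8, 5 and 3 in the same order. The same simulations held 50 genes changed by 3, of which it recovered 36, 44 and 31. They also held 50 changed by 5, of which it recovered 42, 48 and 47. Over these whole simulations it called 10, 6 and 3 unchanged genes. Simulated libraries vary gene by gene, unlike the real ones, whose genes vary together. Alternatives covered the pseudocount on recovered reads, the filter, the scaling, the variance model, sample weights, a replicate block and leaving out each sample. Added after the data were seen were log2 of recovered reads plus 1, voom with and without sample quality weights, a covariate from 4 Y-linked genes, and a fit without p53 KO replicate 1 and Mdm2 C462A replicate 2. Gene positions, lengths and GC content came from GENCODE M21, which is on another build than the files, so no coordinates are given: 19624 row names matched by symbol, 2568 through a synonym and 7763 did not match. Spreadsheet software had turned 27 row names into dates. Symbols are those of the table, some of them older names.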

Results

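Transcript levels were measured by RNA sequencing in mouse embryonic fibroblasts of 3 genotypes. The p53 KO group had 3 libraries, the p53/Mdm2 KO group had 2 and the p53 KO group with the Mdm2 C462A substitution had 2. Mdm2 is the ubiquitin ligase that marks p53 for degradation, and the C462A substitution lies in its RING domain, on which the ligase activity depends. Recovered read totals, with M for reads in units of 1e6, were 40.7, 41.5 and 35.9 M for p53 KO replicates 1, 2 and 3, 39.8 and 28.5 M for p53/Mdm2 KO replicates 1 and 2, and 35.9 and 39.8 M for Mdm2 C462A replicates 1 and 2. The 10 most abundant genes took between 6.03% and 9.08% of a library. The study title frames the question as what Mdm2 does to gene expression, through the Polycomb repressor complex PRC2, in cells without p53.

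The libraries did not all group by genotype. The first principal component, with 44.3% of the variance, separated p53 KO replicate 1 from all others, and the second, with 24.9%, separated Mdm2 C462A replicate 2. In p53 KO replicate 1, 454 genes lay over 4-fold outside the range of the other 6 libraries, 171 above and 283 below, against 96 in Mdm2 C462A replicate 2 and 53 in p53/Mdm2 KO replicate 2. The closest pair across all tested genes joined different genotypes, p53/Mdm2 KO replicate 1 and Mdm2 C462A replicate 1 (Pearson r = 0.9876 across genes, which are not independent replicates). The next closest pair was within a genotype, p53 KO replicates 2 and 3 (r = 0.9855). No pair agreed within counting noise: the lowest chi-square per degree of freedom was 44.2. Separate samples at this depth can exceed that noise whatever their grouping, so the value does not bear on genotype.

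**Figure D1:**
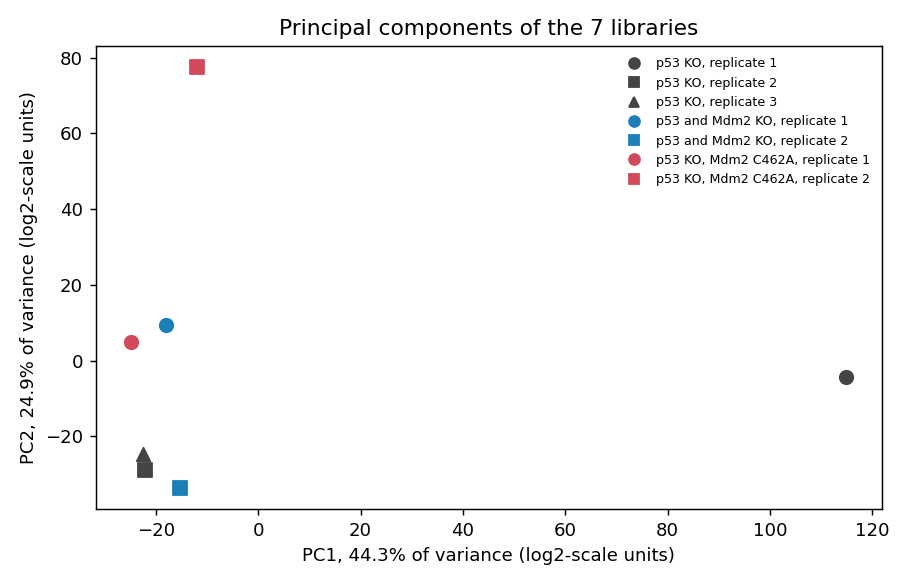
Scores of the 7 libraries on the first and second principal components of the deposited log2-scale values of 16900 genes, with colour for genotype and shape for replicate number. The horizontal axis (44.3% of the variance) sets p53 KO replicate 1 apart and the vertical axis (24.9%) sets Mdm2 C462A replicate 2 apart.

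The targeted genes were read in every library. Mdm2, on chromosome 10, had 1746, 1994 and 1914 normalized reads in the p53 KO replicates, 1575 and 2334 in the p53/Mdm2 KO replicates and 2033 and 2887 in the Mdm2 C462A replicates. Trp53, which encodes p53, ranged from 687.1 to 1775 normalized reads across the 7 libraries. The labels do not describe the knockout alleles. Reads outside a deleted part, or a point substitution, could leave gene totals unchanged, but reads within any deleted part were not examined. These values therefore check no label, and the unreduced Mdm2 level in p53/Mdm2 KO was left unexplained. Mdm4, which encodes a partner of Mdm2, had 663.7 ± 267.1 normalized reads in p53 KO (SD, n = 3), 1011 ± 355.8 in p53/Mdm2 KO (n = 2) and 1590 ± 799.1 in Mdm2 C462A (n = 2), and its differences did not pass limma's test.

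The comparison of p53/Mdm2 KO with p53 KO asks what loss of Mdm2 does where p53 is absent. No single gene was called, and 8 of 30 gene lists passed camera at its preset correlation only. Pla2g4b, a cytosolic phospholipase gene, had 651.4 ± 164.1 normalized reads in p53/Mdm2 KO (n = 2) and 107.5 ± 4.307 in p53 KO (n = 3), a log2 difference of 2.38 (SE 0.237, limma adjusted p = 0.587). It overlaps Jmjd7, so reads of these neighbours are not separated with certainty. Col5a3, a fibrillar collagen gene, had 733.3 ± 141.2 against 4122 ± 1140 normalized reads, a log2 difference of -2.44 (SE 0.306, limma adjusted p = 0.587). Eln, the gene of elastin, had 674.6 ± 535.2 against 5481 ± 1951. Ucp2, which encodes a mitochondrial carrier, had 131.3 ± 138.4 against 2627 ± 990, a log2 difference of -4.46.

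Other genes with large differences and an unadjusted p under 0.01 did not pass the adjusted test either. Higher values in p53/Mdm2 KO were seen for Ica1 (log2 difference 2.20), Tbc1d2 (2.01), Fam110c (1.86) and Spna1 (3.05). Trim30d, a member of a family of similar genes and therefore uncertain, had 276.9 ± 194.9 against 28.73 ± 42.81 normalized reads. Prl2c2 and Prl2c3, near-identical members of the prolactin family whose reads cannot be separated with certainty, had differences of 2.44 and 2.29. Lower values were seen for Gbp1, an interferon-induced GTPase gene with similar relatives (-3.45), Txnip, which encodes a thioredoxin-binding protein (-3.21), its relative Arrdc4 (-2.32), the laminin gene Lama3 (-2.47) and the receptor gene Notch3 (-2.18).

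Among gene lists, 3 were higher and 5 lower in p53/Mdm2 KO by camera, of 30 tested. The hypoxia and glycolysis list was higher, with 26 of 27 members above p53 KO and a median log2 difference of 0.50 (adjusted p = 1.2e-11; adjusted p = 0.78 with an estimated correlation). Its glycolytic gene Pgk1 had 27770 ± 3338 against 18170 ± 2270 normalized reads, and Bnip3, a hypoxia-induced mitophagy gene, had 1583 ± 1085 against 607.2 ± 13.5. The cholesterol synthesis list was higher in 23 of 24 members (median 0.68, adjusted p = 4.2e-06; adjusted p = 0.78 with an estimated correlation), and Cyp51 had 19640 ± 12150 against 10230 ± 4619. The list of Atf4 targets and amino acid genes was higher in 26 of 30 members (median 0.35, adjusted p = 0.015; adjusted p = 0.78 with an estimated correlation).

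The lists on the lower side were interferon response, mitosis, extracellular matrix, DNA replication and smooth muscle contraction, and each had an adjusted p = 0.78 with an estimated correlation. Interferon response genes were lower in 39 of 45 members (median -1.01, camera adjusted p = 4.4e-05), and the 2 mutant libraries lay apart, at 0.63 and -2.47 from the p53 KO mean. Without p53/Mdm2 KO replicate 2 that list turned to a median of 0.54 (adjusted p = 4.12e-06), and without p53 KO replicate 1 its call ended (median -0.52, adjusted p = 0.31). Extracellular matrix genes were lower in 41 of 66 members (median -0.33, camera adjusted p = 3e-04). Of these, 0 were called over all genes and 3 adjusted over the list alone; Mfap5, a microfibril gene, had 351.5 ± 3.68 against 1200 ± 320.4 normalized reads. Smooth muscle genes were lower in 14 of 21 members (median -0.36, camera adjusted p = 0.0041), with 0 called over all genes and 1 adjusted over the list alone, and Synm, an intermediate filament gene, had 107.9 ± 0.3703 against 500.9 ± 71.92. The smooth muscle level of p53 KO replicate 1 (-0.90) lay below both mutant libraries (-0.59 and -0.08). It was 0.26 and 0.64 in p53 KO replicates 2 and 3. Mitosis genes were lower in 29 of 30 members (median -0.31, camera adjusted p = 0.00015) and replication genes in 32 of 35 (median -0.30, camera adjusted p = 9e-04). The mitosis call ended without p53/Mdm2 KO replicate 1 (median -0.12, adjusted p = 0.517), and the replication call without p53 KO replicate 1 (0.01, adjusted p = 0.604) or p53/Mdm2 KO replicate 1 (-0.22, adjusted p = 0.223). The smooth muscle call ended without p53 KO replicate 3 (-0.14, adjusted p = 0.211) or p53/Mdm2 KO replicate 1 (-0.06, adjusted p = 0.517). The extracellular matrix call ended without p53 KO replicate 3 (-0.09, adjusted p = 0.139) and without p53/Mdm2 KO replicate 2, where the median turned to 0.02 (adjusted p = 0.139). The cholesterol and Atf4 calls ended without p53/Mdm2 KO replicate 1 (0.01 and -0.09, adjusted p = 0.815 and 0.711), the Atf4 call also without p53 KO replicate 1 (0.05, adjusted p = 0.786). Sample weights ended the replication (median -0.08, adjusted p = 0.748), Atf4 (0.06, adjusted p = 0.82) and interferon calls (-0.58, adjusted p = 0.0603). Voom with sample quality weights ended the replication (-0.04, adjusted p = 0.758) and Atf4 calls (0.10, adjusted p = 0.594). The Y-linked covariate ended the Atf4 call (0.18, adjusted p = 0.195). Leaving out both outlying libraries ended the replication, interferon, Atf4 and cholesterol calls (0.01, -0.52, 0.05 and 0.29; adjusted p = 0.581, 0.436, 0.743 and 0.0508).

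Polycomb genes gave no call in this comparison in the main test. PRC2 subunit genes had a median log2 difference of 0.01 and a mean of -0.01, of opposite sign (7 of 12 members higher, camera adjusted p = 0.84), PRC1 subunit genes -0.11 (8 of 22 higher, adjusted p = 0.45), and the developmental transcription factor genes that are typical Polycomb targets 0.00 (53 of 106 higher, adjusted p = 0.24). Only 106 of the 187 listed developmental genes passed the filter on mean reads, so those with fewer reads were not tested in any comparison. Hox genes were higher in 25 of 35 members (median 0.53, adjusted p = 0.19), a value that rests on p53 KO replicate 1, whose Hox level was -1.12 against 0.69 and 0.43 in the other p53 KO libraries. The Hox median turned to -0.22 without that library. At the preset correlation the Hox list passed without p53 KO replicate 2 (0.89, camera adjusted p = 0.00954), and its median was 0.87 without p53/Mdm2 KO replicate 1. In the main fit it had a camera adjusted p = 0.78 with an estimated correlation. In these lists 0 members were called over all genes and 0 adjusted over the list alone. In limma 0 of 16900 genes had an adjusted p under 0.05, and 507 had an unadjusted p under 0.05, where 845 are expected with no difference. Without p53 KO replicate 1 that count was 784. By voom the count of called genes was also 0.

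**Figure D2:**
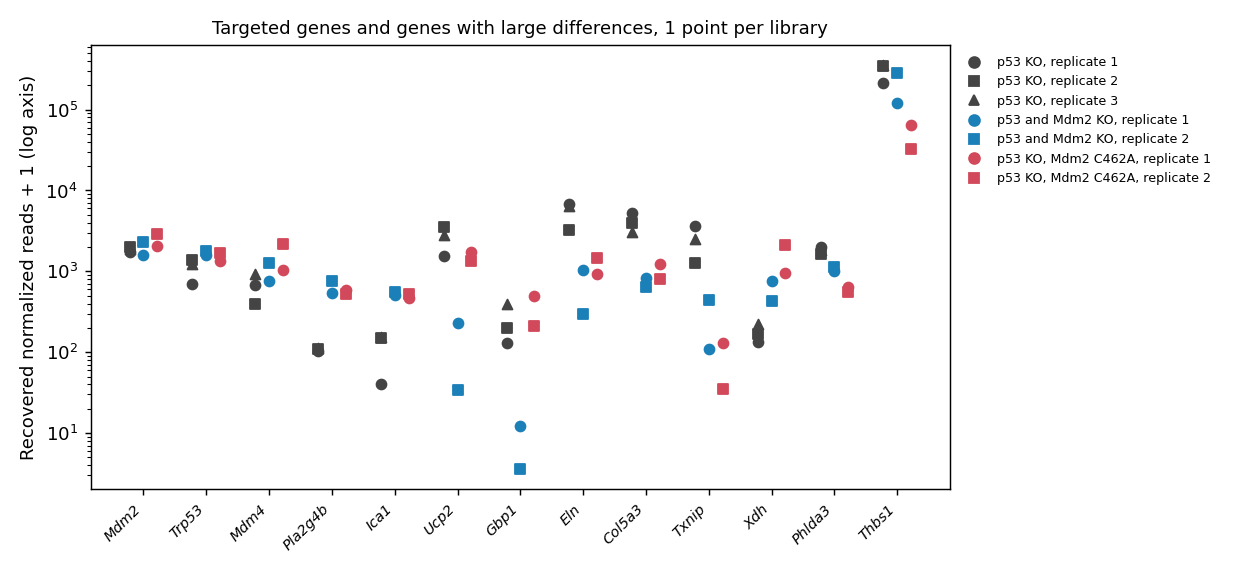
Recovered normalized reads plus 1 (log axis) of the targeted genes, of Mdm4 and of genes with large differences, with 1 point per library, colour for genotype and shape for replicate number. Mdm2 lies between 1575 and 2887 in all 7 libraries, while Ucp2 is lower in both p53/Mdm2 KO libraries (229.2 and 33.48) than in the other libraries.

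The comparison of p53 KO with Mdm2 C462A against p53 KO asks what the substitution in the RING domain does in the same background. Mitosis genes were lower throughout: all 30 members of the list lay below p53 KO, with a median log2 difference of -1.27. Mki67, the proliferation marker gene, had 5944 ± 4088 normalized reads in Mdm2 C462A (n = 2) and 15670 ± 1851 in p53 KO (n = 3), and Top2a, the gene of a DNA topoisomerase, had 8160 ± 3438 against 16300 ± 120.2. Smooth muscle genes were lower in 20 of 21 members. Their list level was -0.90 in p53 KO replicate 1, near the Mdm2 C462A libraries (-1.01 and -1.18). It was 0.26 and 0.64 in p53 KO replicates 2 and 3. Myl9, a myosin light chain gene, had 4182 ± 1547 against 20760 ± 3697, a log2 difference of -2.34.

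Mitosis genes passed camera (adjusted p = 4.6e-25), and the call was lost with the estimated correlation of 0.81 between members (adjusted p = 0.87 with an estimated correlation). Of the 30 members, 0 were called over all genes and 30 adjusted over the list alone. Cdc20, an activator of the anaphase-promoting complex, had a log2 difference of -1.26, the kinase gene Plk1 -1.45 and Melk -1.53. DNA replication genes were lower in 35 of 35 members (median -0.86, camera adjusted p = 1.1e-14; adjusted p = 0.87 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. With both outlying libraries left out the medians shrank to -0.64 for mitosis and -0.20 for replication genes, and both lists still passed. The replication level was 0.62 in p53 KO replicate 1 against -0.22 and -0.40 in the other p53 KO libraries. Rrm1, a ribonucleotide reductase gene, had 6476 ± 632.2 against 11260 ± 84.52. The smooth muscle list (median -1.02, camera adjusted p = 9e-10; adjusted p = 0.87 with an estimated correlation) had 0 members called over all genes and 6 adjusted over the list alone. In fry's mixed test, which asks whether any member changed in either direction, this was the 1 list that passed (mixed adjusted p = 0.014). Extracellular matrix genes were lower in 42 of 66 members (median -0.58, camera adjusted p = 0.00021; adjusted p = 0.87 with an estimated correlation), with 3 adjusted over the list alone, a call that ended without p53 KO replicate 3 (median -0.34, adjusted p = 0.0618). Thbs1, the gene of thrombospondin, had 48860 ± 22400 against 305800 ± 79180.

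On the higher side, Atf4 and amino acid genes were above p53 KO in 28 of 30 members (median 1.19, camera adjusted p = 5e-10; adjusted p = 0.87 with an estimated correlation). Ddit3, a stress-induced transcription factor gene, had 3686 and 21320 normalized reads in Mdm2 C462A replicates 1 and 2 and 1380 ± 345.9 in p53 KO. Cholesterol synthesis genes were higher in 24 of 24 members (median 0.92, camera adjusted p = 1.3e-06; adjusted p = 0.87 with an estimated correlation), and Insig1 had 12130 ± 3802 against 4941 ± 488. Hypoxia and glycolysis genes were higher in 19 of 27 members (median 0.60, camera adjusted p = 0.0033; adjusted p = 0.87 with an estimated correlation). The cholesterol and hypoxia calls ended without Mdm2 C462A replicate 1 (medians 0.53 and 0.44, adjusted p = 0.115 and 0.113), and the Atf4 call ended with both outlying libraries left out (median 0.33, adjusted p = 0.1). The list levels in Mdm2 C462A replicate 2, the library that stands apart, were the farthest from p53 KO for mitosis (-1.75) and Atf4 genes (1.84). For cholesterol genes the levels were 1.40 and 0.44 in Mdm2 C462A replicates 1 and 2. They were -0.82, 0.34 and 0.49 in p53 KO replicates 1, 2 and 3, so the mutant and control ranges overlapped.

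The largest differences of single genes did not pass the adjusted test. Txnip had 80.85 ± 65.69 normalized reads against 2461 ± 1160, a log2 difference of -4.69 (SE 0.735, limma adjusted p = 0.437). Lower values were also seen for Wisp2 (-3.67), the collagen gene Col10a1 (-3.65), Mrvi1 (-2.85), Rap1gap2 (-2.68) and the calcium channel gene Cacna1h (-2.55). Phlda3, a p53 target gene, had 603.7 ± 59.18 against 1831 ± 176.9 (log2 difference -1.57, limma adjusted p = 0.3). Xdh, the gene of xanthine dehydrogenase, had 1535 ± 837.3 against 173.9 ± 43.51 (2.92), and the ceruloplasmin gene Cp 1660 ± 1361 against 207.5 ± 45.38 (2.62). Angptl6 (3.05) and Trim30d (2.99) were also higher, as were the entries Ugt1a6a (3.66), Ugt1a7c (3.52) and Ugt1a6 (3.34), which share exons, so that their reads cannot be separated.

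Polycomb lists and p53 targets gave no call here in the main test. PRC2 subunit genes were lower in 10 of 12 members (median -0.12, camera adjusted p = 0.088), and Ezh2, the catalytic subunit gene, had 1255 ± 267.3 against 1971 ± 205.2 normalized reads. PRC1 subunit genes had a median of -0.10 (adjusted p = 0.57), developmental transcription factor genes 0.09 (57 of 106 higher, adjusted p = 0.98) with 0 called over all genes and 1 adjusted over the list alone, and Hox genes -0.12 (adjusted p = 0.15). In the main fit the Hox list had a camera adjusted p = 0.93 with an estimated correlation. At the preset correlation it passed on the lower side without p53 KO replicate 1 (median -1.09, adjusted p = 5.66e-10), with sample weights (-0.92, adjusted p = 3.3e-05) and by voom with sample quality weights (-1.11, adjusted p = 0.000627). With both outlying libraries left out, Hox genes had a median of -1.13. Without Mdm2 C462A replicate 2 they passed at a median of -0.02 (adjusted p = 0.0416). The p53 target list had a median of 0.11 (adjusted p = 0.68), with 0 called over all genes and 1 adjusted over the list alone. In limma 0 of 16900 genes had an adjusted p under 0.05 and 1761 an unadjusted p under 0.05. Without Mdm2 C462A replicate 2 that count was 638. By voom the count of called genes was 0.

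**Figure D3:**
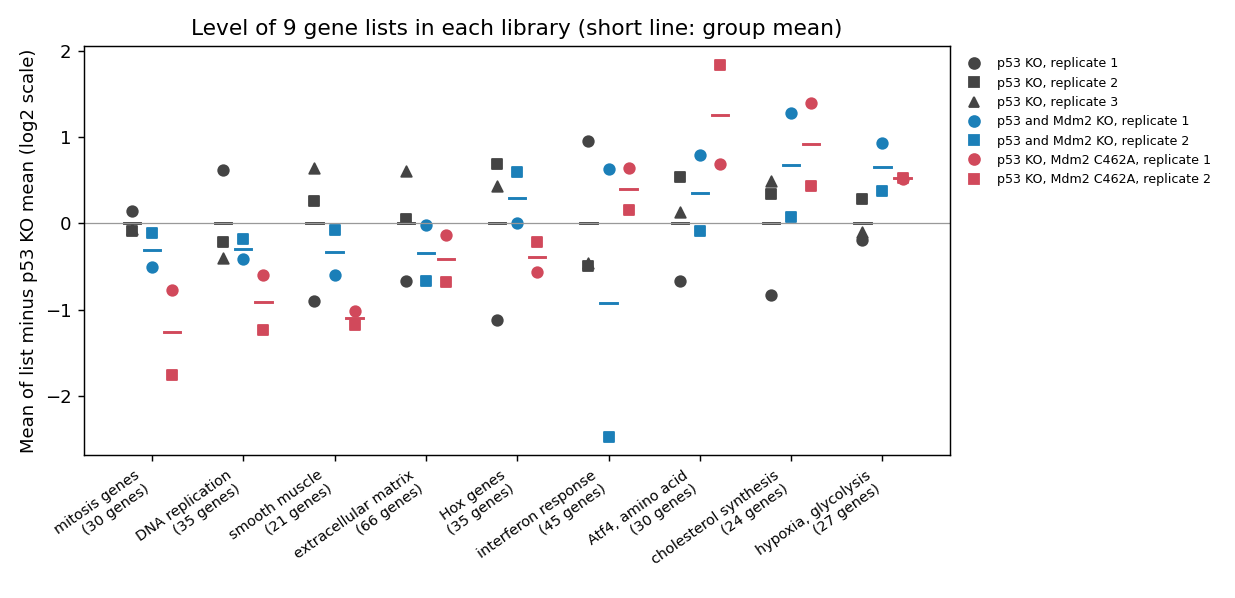
Mean level of 9 gene lists in each library relative to the p53 KO mean (log2 scale), with 1 point per library and a short line for the group mean. Mitosis genes lie at -0.77 and -1.75 in Mdm2 C462A, below the 3 p53 KO libraries, and interferon response genes lie at 0.63 and -2.47 in the p53/Mdm2 KO libraries.

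The direct comparison of Mdm2 C462A with p53/Mdm2 KO asks whether the substitution and the loss of Mdm2 differ. Mitosis genes were lower with the substitution in 30 of 30 members (median -0.95), replication genes in 35 of 35 (median -0.58) and smooth muscle genes in 19 of 21 (median -0.77). Hox genes were lower in 33 of 35 members (median -0.66) and interferon response genes higher in 44 of 45 (median 1.18). Ucp2 had 1557 ± 283.3 normalized reads with the substitution (n = 2) and 131.3 ± 138.4 without Mdm2 (n = 2), and Gbp1 350.8 ± 195.6 against 6.854 ± 6.052.

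These lists passed camera, with adjusted p = 3.8e-26 for mitosis, 1.2e-11 for replication, 3.3e-08 for smooth muscle, 0.00032 for Hox and 2.3e-09 for interferon response genes. All of these calls were lost: adjusted p = 0.79 with an estimated correlation for mitosis, replication, smooth muscle and Hox genes, and adjusted p = 0.84 with an estimated correlation for interferon response genes. Atf4 and amino acid genes were higher in 29 of 30 members (median 0.76, camera adjusted p = 3.4e-08; adjusted p = 0.79 with an estimated correlation). Adipogenic genes (12 of 16 higher, camera adjusted p = 0.0075), glial and neural crest markers (10 of 11 higher, camera adjusted p = 0.0074) and PRC2 subunit genes (10 of 12 lower, camera adjusted p = 0.0097) also passed, each with an adjusted p = 0.79 with an estimated correlation. Cebpb, an adipogenic transcription factor gene, had 2839 ± 1325 against 1084 ± 599.1 normalized reads, and Mbp 1267 ± 768 against 462.7 ± 126.3. In all 9 passing lists 0 members were called over all genes and 0 adjusted over the list alone. Without p53/Mdm2 KO replicate 2 the interferon list turned to a median of -0.18 (adjusted p = 0.0773), and the PRC2, Hox and adipogenic calls ended at medians of the same direction (-0.15, -0.45 and 0.33; adjusted p = 0.0793, 0.0687 and 0.0972). The Hox call also ended without Mdm2 C462A replicate 1, at an unreduced median (-0.68, adjusted p = 0.116), and the PRC2, Atf4 and glial calls without Mdm2 C462A replicate 2 (medians -0.14, 0.20 and 0.31; adjusted p = 0.0846, 0.0976 and 0.0846) and with both outlying libraries left out (the same medians; adjusted p = 0.156, 0.082 and 0.0791).

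With both outlying libraries left out the medians shrank to -0.47 for mitosis and -0.28 for replication genes, which still passed. Developmental transcription factor genes gave no call (48 of 106 higher, median -0.09, camera adjusted p = 0.4) except without Mdm2 C462A replicate 1 (median -0.44, adjusted p = 0.0407), nor did PRC1 subunit genes, whose median (-0.03) and mean (0.02) differ in sign (camera adjusted p = 0.9).

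Among single genes, Odz4 (log2 difference 3.02), Syngr1 (1.97) and the transporter gene Abca8b (1.86) were higher with the substitution, and the connexin gene Gjb2 (-2.04), Pcolce2 (-1.79), Chst1 (-1.66) and Cav1, the gene of caveolin (-1.66), were lower, none past the adjusted threshold. In limma 0 of 16900 genes had an adjusted p under 0.05 and 503 an unadjusted p under 0.05. That count was 61 without p53/Mdm2 KO replicate 2, 136 without Mdm2 C462A replicate 2, 1083 without p53/Mdm2 KO replicate 1, 1519 without Mdm2 C462A replicate 1, 926 without p53 KO replicate 1, and 324 and 311 without p53 KO replicates 2 and 3. By voom the count of called genes was 0.

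The effects of both Mdm2 mutants against the same p53 KO libraries correlated across genes with r = 0.605, and genes are not independent replicates. Unchanged groups simulated against the same controls gave r = 0.401 on average. The covariance was 0.171 against a simulated 0.0875. It was 0.301 without p53 KO replicate 2, 0.288 without p53 KO replicate 3 and 0.101 without p53/Mdm2 KO replicate 1. No values were simulated for these smaller sets, so they cannot be set against 0.0875. Without p53 KO replicate 1 the observed r was 0.575 against a simulated 0.503, and the covariance 0.145 against a simulated 0.0731. Among genes with an unadjusted p under 0.05, 140 were higher and 128 lower in both mutants, and 0 went in opposite directions. Simulated sets gave 82.5, 85.7 and, in opposite directions, 10.5 on average (3 to 21), and independent lists would share 12.7 and 13.7 in the same direction. Synm, Col5a3 and Mfap5 were among the genes lower in both mutants. The 3 controls are too few to split, so part of the excess may come from the shared controls. Without p53/Mdm2 KO replicate 1 the correlation was 0.277, again with no simulated value for that set of libraries.

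Sex-linked genes differed within each genotype. Xist, the RNA that silences an X chromosome in female cells, had 2517, 60.33 and 42380 normalized reads in p53 KO replicates 1, 2 and 3, 2492 and 55500 in p53/Mdm2 KO replicates 1 and 2, and 38330 and 89.96 in Mdm2 C462A replicates 1 and 2. Ddx3y, on chromosome Y, had 1.818, 1501 and 6.472, then 1100 and 7.725, then 5.012 and 1699 in the same order. Eif2s3y, Kdm5d and Uty were likewise high in p53 KO replicate 2, p53/Mdm2 KO replicate 1 and Mdm2 C462A replicate 2. In the same order Eif2s3y had 0.9089, 1705, 5.393, 1712, 7.725, 1.002 and 1930. Kdm5d had 0.9089, 419.5, 0, 445.4, 3.863, 4.009 and 653.5. Uty had 4.545, 862.3, 26.96, 877.7, 34.76, 14.03 and 1360. Tsix, on chromosome X, had 14.54, 1.856, 745.3, 56.6, 1007, 300.7 and 0.882. The Y-linked values argue against a single embryo as the source of all libraries of a genotype. Library p53/Mdm2 KO replicate 1 held both Y-linked reads and 2492 normalized reads of Xist. In p53 KO replicate 1 there were 2517 normalized reads of Xist, with at most 4.545 normalized reads of any of these Y-linked genes.

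**Figure D4:**
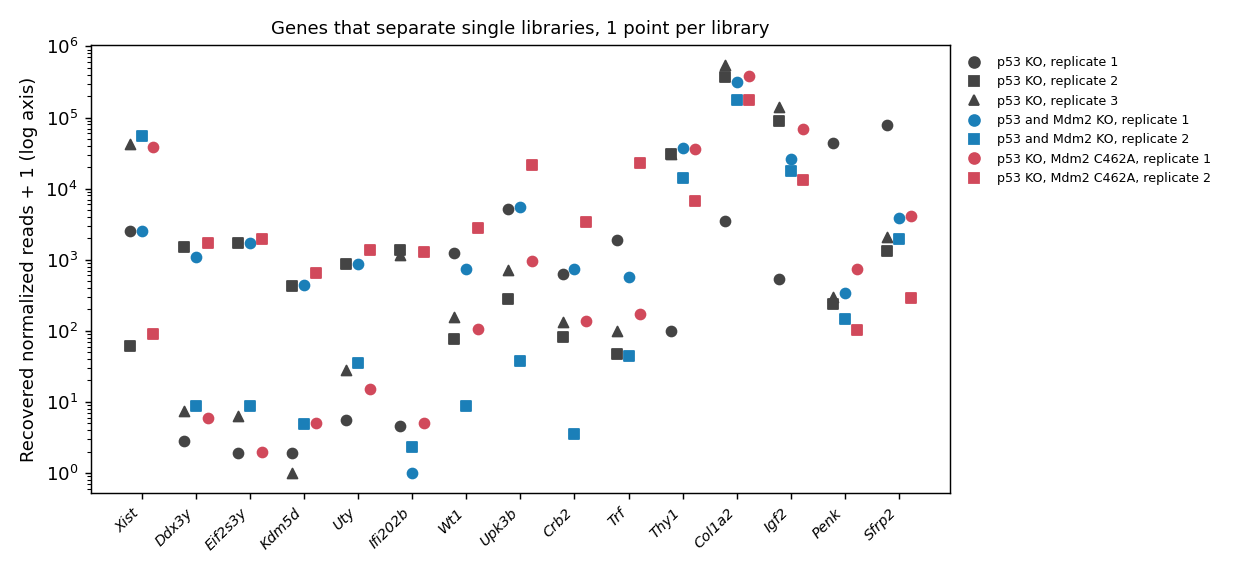
Recovered normalized reads plus 1 (log axis) of sex-linked genes and of genes that separate single libraries, with 1 point per library, colour for genotype and shape for replicate number. Ddx3y is at 1100 to 1699 in 3 libraries and at 7.725 or less in the other libraries, and Upk3b reaches 21600 in Mdm2 C462A replicate 2.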

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

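Settings chosen after seeing the data were the log2 of recovered reads plus 1, both voom fits, the Y-linked covariate and leaving out both outlying libraries. The count of 0 called genes held in all 3 comparisons under every setting but 1. With both outlying libraries left out, p53/Mdm2 KO against p53 KO had 1 call, Ifi202b (log2 difference -6.70). Its low control, p53 KO replicate 1 (3.636 normalized reads, mutants 0 and 1.288), was left out. The planned edgeR (2 scalings) and DESeq2 tests were not run, and voom called 0 genes in each comparison. Under all alternatives 3679 values of named genes, without those taken for highest mean, kept their direction without a call. Most of these genes were picked for separated replicates or small p, which favours this. For Mdm2 in p53/Mdm2 KO against p53 KO, 5 changed sign without a call. Of the list results, 1869 kept direction and side of the threshold, 35 lost their call, 95 gained 1, 15 reversed and 146 turned without a call; no cause was tested except where fewer samples were used.

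For p53/Mdm2 KO against p53 KO the 507 genes at an unadjusted p under 0.05 became 766 with no filter, 921 with sample weights, 852 by voom with sample quality weights and 1091 with both outlying libraries left out, and between 345 and 784 on leaving out single libraries. The 8 passing lists became 0 with an estimated correlation, 0 by fry and 0 by mixed fry, 5 with sample weights, and between 8 and 15 on leaving out single libraries. For Mdm2 C462A against p53 KO the 1761 genes ranged from 638 to 2293 on leaving out single libraries. The 7 lists became 0 with an estimated correlation, 0 by fry, 1 by mixed fry, 13 with sample weights, 12 by voom with sample quality weights, 11 with both outlying libraries left out and between 6 and 16 on leaving out single libraries. Between the Mdm2 mutants the 503 genes became 787 with no filter and ranged from 61 to 1519 on leaving out single libraries. The 9 lists became 0 with an estimated correlation, by fry and by mixed fry, and between 9 and 15 on leaving out single libraries. The correlation of mutant effects ranged from 0.277 to 0.73 on leaving out single libraries. No scaling moved the median of all genes by over 0.1.

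Some lists reversed; these are median log2 differences, with the lowest and highest value on leaving out single libraries, and the cause was not tested. In p53/Mdm2 KO against p53 KO, replication genes ran from -0.509 (without p53 KO replicate 3) to 0.014 (without p53 KO replicate 1, and 0.014 with both outlying libraries left out). Imprinted genes ran from -0.285 (without p53 KO replicate 1, or with both outlying libraries left out) to 0.791 (without p53 KO replicate 3). Leaving out p53/Mdm2 KO replicate 1 or 2 gave -2.20 or 0.54 for interferon, -1.27 or 1.05 for antigen presentation, -0.0938 or 0.626 for Atf4 genes and -1.16 or 0.724 for macrophage markers, the last also at 0.692 with the replicate block. Leaving out p53 KO replicate 3, which the block fits exactly, gave the same value. In Mdm2 C462A against p53 KO, imprinted genes ran from -0.371 (without p53 KO replicate 1) to 0.892 (without p53 KO replicate 2). Between the mutants, leaving out p53/Mdm2 KO replicate 1 or 2 gave 2.71 or -0.177 for interferon, 1.38 or -0.689 for antigen presentation, 0.749 or -0.311 for cholesterol and 0.652 or -0.344 for epithelial genes. Imprinted genes there were at 0.19 with both outlying libraries left out.

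Deviations of same-numbered libraries correlated between -0.16 and 0.20. In a group of 2 libraries the deviations mirror each other, so these values cannot exclude that replicate numbers pair the samples. With the replicate number as a block the counts at an unadjusted p under 0.05 were 442, 1486 and 279, and 0 genes were called, while 10, 6 and 10 lists passed. The block ended the smooth muscle (-0.14, adjusted p = 0.358) and extracellular matrix calls (-0.09, adjusted p = 0.0511) in p53/Mdm2 KO against p53 KO and the hypoxia call in Mdm2 C462A against p53 KO (0.45, adjusted p = 0.0583), and Hox genes passed in p53/Mdm2 KO against p53 KO (0.61, adjusted p = 0.0112). Replicate number 3 occurs only in p53 KO, so the block fits that library exactly and group differences leave it out. The smooth muscle and extracellular matrix medians were the same without that library. Their lost calls cannot be told apart from the loss of that control, and do not bear on pairing. Depth limits little here, as the shallowest library held 28.5 M reads. With both outlying libraries left out, 1 sample stood alone for Mdm2 C462A, and it was assumed to vary like the other groups, as was the remaining sample wherever 1 of 2 was left out.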

Other observations

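The tests of sequencing depth, of a minority of other cells and of the Mdm2 C462A genotype were chosen after the values they measure had been seen, as were the genes named for single libraries. In p53 KO replicate 1 the opioid precursor gene Penk had 43620 normalized reads against at most 729.7 in the other libraries, and Sfrp2, a secreted Wnt modulator, 78000 against at most 4122. The fat cell genes Fabp4 (4328) and Pparg (3048) were also highest there. Thy1, a fibroblast surface marker, had 99.07 normalized reads in that library and at least 6592 in the others, and Col1a2 had 3456 against at least 175100, while Col1a1 was at 458000. The imprinted genes Igf2 (527.2), Ndn (3.636) and Cdkn1c (19.09) were lowest in that library.

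Ifi202b, an interferon-inducible gene that differs between mouse strains, had 1361 and 1148 normalized reads in p53 KO replicates 2 and 3 and 1286 in Mdm2 C462A replicate 2. It had 3.636 in p53 KO replicate 1, 0 and 1.288 in p53/Mdm2 KO replicates 1 and 2, and 4.009 in Mdm2 C462A replicate 1. A count of 0 there allows up to 2.78 normalized reads. These are values, and no explanation was tested.

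The distance of p53 KO replicate 1 from the other 6 libraries does not come from low depth, since its 40.7 M reads exceed the lowest of the others. A trend on gene length and GC content took 2.87% of the variance of its deviation, and 94.7% of the 454 genes concerned had both values. RNA from a minority of other cells argues against itself as a whole cause, since it can lower no gene by more than its own share, and 106 genes with at least 500 normalized reads in every other library lay over 4-fold below the lowest of them. The limit of over 100 such genes was set after they had been seen and was only just passed. A culture made mostly of other cells, or a mislabelled sample, stays open, and no biological explanation was tested because the label names only the genotype.

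Mesothelial-type markers, such as Upk3b (21600 normalized reads) and Wt1 (2832), were highest in Mdm2 C462A replicate 2. The genotype argues poorly for this: the marker median of Mdm2 C462A replicate 1, minus that of the highest library of another genotype, was -2.42 on the log2 scale. Mesothelial-type cells in that culture are a candidate explanation: 14 markers other than those in which the pattern was seen had a median log2 difference of 1.80 from the other 6 libraries, 13 of them above the mean of the others and 6 highest in this library. At least Krt19 among these markers had been examined before, as a member of the epithelial gene list. The median level of the 14 markers was nearly equal in p53/Mdm2 KO replicate 1 (8.53 against 8.73), where Krt8, Krt18, Aldh1a2, Muc16 and Slpi were highest, so the trait is not particular to 1 culture. The hypothesis was found and tested on the same libraries.

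The number of genes with an unadjusted p under 0.05 in both Mdm2 mutants in the same direction was 268. Of the 240 such genes with a known position, 0% lay within 10 Mb of Mdm2, against 0.646% of all tested genes. Most of them are therefore not genes close to Mdm2 that carry strain variants of their own. With so small a share among all genes, the test had little power to show an excess. It did not cover linked variants that act on distant genes. The shared p53 KO libraries may account for the 268 genes. The count exceeds all 100 simulated sets (highest 193), which had been set beforehand as evidence against this explanation, but simulated libraries vary gene by gene, and 17 of 100 splits of the real libraries gave as many, up to 738, so that bound was too narrow and the shared libraries cannot be told apart from a common effect.

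Regrouping the same libraries gave as many genes at an unadjusted p under 0.05 in 58 of 100 splits for p53/Mdm2 KO against p53 KO (507, highest other split 1972). It did so in 8 of 100 splits for Mdm2 C462A against p53 KO (1761, highest other 2786) and in 51 of 79 distinct splits between the Mdm2 mutants (503, highest other 2273). Chance could not be excluded for any of these 3 counts.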
